A study of Mus musculus with 21 samples.

How the data were processed

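The series holds RNA sequencing of mouse acute myeloid leukaemia cells in 3 experiments, PRC2 inhibition and Kdm5b knockdown in NUP98-NSD1 cells and Kdm5b overexpression in MLL-AF9 cells, with 9, 6 and 6 libraries. Per the labels, 1 µg of total RNA went into libraries made with 1 of 2 named kits, and which kit made which library is not stated. Per the submitters' processing notes, reads were aligned to mm10 (GRCm38.p4) with STAR 2.4.2, quantified with Salmon 0.1.19 and normalised with DESeq2 1.38.2. The deposited values of all 3 tables are on a log2 scale after a variance-stabilising transformation by the authors. The lowest value of each table, taken by genes with no reads in a library, was 6.88278, 7.43603 and 8.18232 for the inhibitor, knockdown and overexpression tables, so genes of low count are compressed towards it.

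The closed form of the transformation, with the dispersion implied by each table's lowest value, was undone to give normalised read counts. Within each library these were whole multiples of 1 step for 100% of values at a tolerance of 0.05, which gave the whole counts and the depth of every library. Levels and ratios in the text are in these normalised counts, while tests used the deposited values. Columns were matched to samples by their names, and replicate numbers came from the titles. The tables held 14178, 15623 and 13949 genes. Genes at least 1 log2 unit above the lowest value of the table in as many libraries as the smallest group were tested, which corresponds to 59.0, 86.6 and 145 normalised counts and left 10694, 10810 and 9458 genes.

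Each table was fitted with limma 3.58.1 in R 4.3.3 (1 mean per group, eBayes with trend), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. UNC1999 and JQEZ5 were each compared with DMSO and with each other, shKdm5b with shEV, and WT and H499A each with EV and with each other. On simulated data, 200 genes were changed in values with the spread of each experiment. Changes of 0.25 log2 units were recovered in 77.6% to 82.1% of genes with 3 libraries per group and in 98.5% to 100% in the overexpression experiment, larger ones in 100%, with 8 to 19 false calls. Libraries of a group differed by a chi-square per degree of freedom of 1.50 to 18.3, above the 1 that counting error alone gives, and correlated at a Pearson r of 0.9943 to 0.9989.

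The gene lists covered PRC2 subunits, regulators of H3K4 and H3K27 methylation outside PRC2, CDK inhibitors and the RB family, HOX cluster genes, stem cell and leukaemia self-renewal genes, neutrophil and granule genes, monocyte and macrophage genes, S phase genes, G2 and M phase genes, MYC targets and ribosome biogenesis genes, p53 targets, interferon-stimulated genes, MHC class I and class II presentation, cholesterol synthesis, integrated stress and unfolded protein responses, and developmental transcription factors typical of PRC2 targets. Markers of erythroid, megakaryocyte, mast, basophil and eosinophil, B, T and NK, dendritic, and stromal and endothelial cells made 7 more. Members were written down before the data were examined, as were the comparisons, tests and alternatives except where stated. Lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of each comparison (16 in NUP98-NSD1 cells, 17 in MLL-AF9 cells). Camera asks whether a list moves more than other genes. Fry, an alternative, asks whether the members move on balance 1 way and does not compare them with other genes. Camera with a correlation estimated from the libraries was a further alternative, and its adjusted p is given wherever it ended a call. That estimate rests on 6, 4 and 3 residual degrees of freedom in the inhibitor, knockdown and overexpression experiments. A miss with it therefore does not show that a list was unmoved.

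The genes named are Kdm5b and Ezh2 in every comparison, the 6 largest changes each way (4 each way between treated groups) among called genes whose libraries did not overlap between groups, and up to 4 called members with the lowest adjusted p in each list described. Predicted genes, pseudogenes and bare identifiers were left out, and some genes that the rule chose are not reported here. Chance separates 3 from 3 libraries without overlap in 10% of genes. Gene coordinates came from GENCODE M21, where 61 of 64 such genes were found under the symbols of the tables. Overlaps between comparisons that share controls were set beside independent lists and beside 100 simulated unchanged groups drawn against the same controls.

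Alternatives were no filter, a filter at 2 log2 units, median centring, quantile normalisation, eBayes without the trend or with robust settings, a fold minimum of 1 log2 unit, the replicate number as a block, only the 2 groups compared, leaving out each library, and camera with an estimated correlation or fry for lists. A voom fit of the recovered counts was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads were not used here, and other assays of the study were not analysed here.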

Results

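RNA was sequenced from 21 libraries of established mouse acute myeloid leukaemia cells. NUP98-NSD1 cells, transformed by a fusion of the nucleoporin NUP98 with the histone methyltransferase NSD1, made up 15 of them. They were given DMSO, UNC1999 or JQEZ5, both inhibitors of the histone H3 lysine 27 methyltransferase complex PRC2, at 3 µM for 4 days (3 libraries each), or an empty lentiviral vector (shEV) or an shRNA against Kdm5b (shKdm5b; 3 libraries each). MLL-AF9 cells, transformed by a fusion of the methyltransferase MLL with AF9, carried an empty retroviral vector (EV), wild-type Kdm5b (WT) or the demethylase-dead mutant H499A (2 libraries each). Total counts ran from 12.8 to 18.9 M per library in the inhibitor experiment, from 21.3 to 34.8 M in the knockdown and from 17.3 to 20 M in the overexpression. The labels do not say whether replicates came from separate cultures, so the p-values may measure technical spread only. Levels are normalised read counts with their SD over libraries, and log2 changes with their SE are on the variance-stabilised scale, which compresses genes of low count.

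The targeted gene was read first in every library. Kdm5b encodes a histone H3 lysine 4 demethylase and lies on chromosome 1 of GRCm38 at 134560171 to 134635285 on the plus strand (ENSMUSG00000042207.17, GENCODE M21). In the knockdown it fell by 61.5%, from 74.48 ± 17.8 with shEV to 28.69 ± 5.44 with shKdm5b (n = 3 each, lower in 3 of 3 libraries; limma adjusted p = 0.00401). This gene lay below the expression filter of the knockdown experiment, so its p comes from a fit of all 15623 genes. It rests on 17 to 34 reads per shKdm5b library and 71 to 112 per shEV library. In MLL-AF9 cells Kdm5b was at 121.4 ± 9.89 with EV, 1413 ± 4.48 with WT and 294 ± 21.5 with H499A (n = 2 each). WT was thus 11.6-fold and H499A 2.42-fold above EV, with limma adjusted p of 3.71e-23 and 6.91e-11, and WT was 4.8-fold above H499A (limma adjusted p = 3.02e-20). The labels do not say whether the introduced Kdm5b is of mouse sequence, so its reads may not all be counted and these folds may be too low. Exact 2-sided permutation tests of single genes cannot go below p = 0.1 for 3 against 3 libraries or 0.333 for 2 against 2, and each of these Kdm5b differences gave that smallest value.

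Both PRC2 inhibitors were compared with DMSO to ask what loss of PRC2 activity does to these cells, Kdm5b included. Kdm5b rose 1.46-fold with UNC1999, from 607 ± 14.9 to 886 ± 14.7 (n = 3 each; limma adjusted p = 1.65e-07). With JQEZ5 it was 658 ± 8.64, a log2 difference from DMSO of 0.09 ± 0.04 that did not pass (limma adjusted p = 0.112). Tested directly, Kdm5b was 1.35-fold higher with UNC1999 than with JQEZ5 (limma adjusted p = 5.49e-06). Ezh2, the main catalytic subunit of PRC2, fell by 24.1% with UNC1999 (limma adjusted p = 3.23e-05). With JQEZ5 its log2 difference was 0.00 ± 0.05 (limma adjusted p = 0.998), and the direct test between inhibitors gave a log2 difference of -0.35 ± 0.05 (limma adjusted p = 6.65e-05). The plot of Kdm5b per library shows all 3 experiments.

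**Figure D1:**
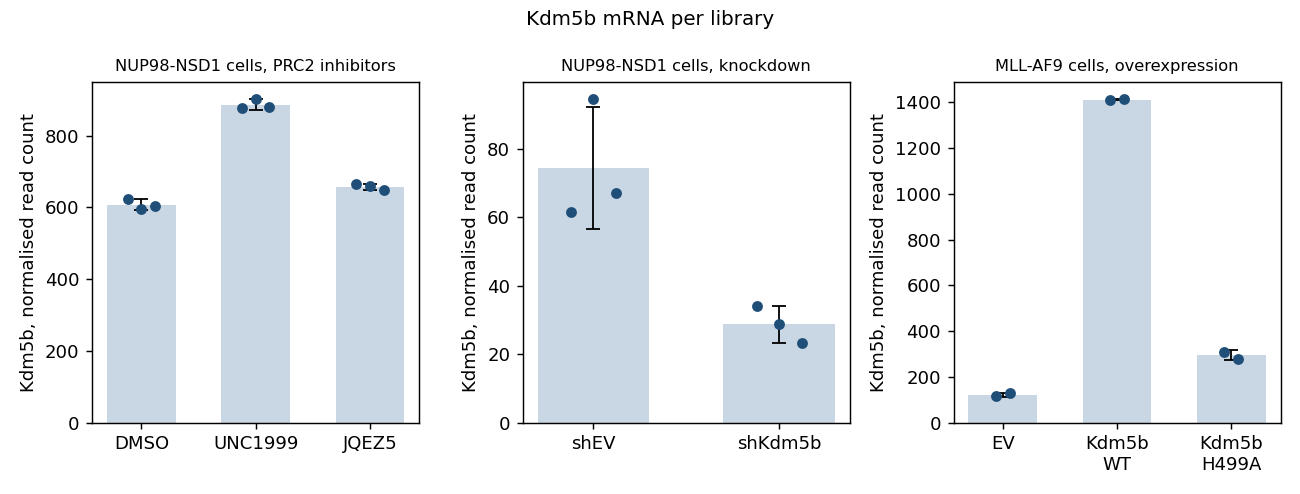
Kdm5b mRNA as normalised read count (vertical axis, from 0, on a separate scale for each experiment). Points are libraries, bars are group means and error bars are SD. UNC1999 libraries lie above every DMSO and JQEZ5 library, shKdm5b libraries lie below every shEV library, and H499A (mean 294) lies between EV (mean 121.4) and WT (mean 1413).

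UNC1999 was compared with DMSO over all genes. Gpnmb, a lysosomal glycoprotein of macrophages, rose 13.2-fold, from 5220 ± 69.7 to 69000 ± 1190 (n = 3 each; log2 change 3.67 ± 0.02). The arginase Arg1 rose 11.7-fold, the interleukin-7 receptor Il7r 15.6-fold, the itaconate-producing enzyme Irg1 6.22-fold, osteopontin (Spp1) 5.33-fold and von Willebrand factor (Vwf) 7.44-fold. Of 30 monocyte and macrophage genes tested, 26 rose and 2 fell (28 and 2 adjusted over the list alone), among them Cd68 (3.68-fold), the lysosomal protease Ctsb (2.32-fold) and the macrophage surface receptor Adgre1 (3.74-fold). The steepest falls were in Cxcr2, a chemokine receptor of neutrophils, from 797 ± 28.9 to 181 ± 15.6, then in Lars2, Mir6236, Xirp1, Sgip1 and the integrin Itgb3, whose levels were 0.502, 0.515, 0.309, 0.565 and 0.476 times those in DMSO. Over these 12 genes the limma adjusted p ran from 2.79e-21 to 6.82e-07.

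Proliferation genes went the other way with UNC1999. All 30 genes of G2 and M phase fell, with Bub1b at 0.62 and Top2a at 0.685 times the DMSO level, and 29 of 30 S phase genes fell, with the replicative helicase subunits Mcm3 at 0.68 and Mcm7 at 0.641. Of 30 MYC target and ribosome biogenesis genes, 28 fell and 1 rose, with the nucleolar genes Nolc1 at 0.741 and Ddx21 at 0.766. Of 22 cholesterol synthesis genes, 14 fell, among them Fdps (0.717) and Idi1 (0.681), and 1, the squalene epoxidase Sqle, rose 1.52-fold. Each count in these 4 lists was the same when adjusted over the list alone. The monocyte, S phase, G2 and M phase and MYC lists had camera adjusted p of 6.83e-18, 7.59e-16, 1.43e-17 and 1.32e-09, each 0.0027 with an estimated correlation, and the cholesterol list 0.00275, with adjusted p = 0.034 with an estimated correlation.

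Among developmental regulators, 6 of 10 HOX cluster genes fell with UNC1999 and none rose, the same counts as when adjusted over the list alone. Hoxa9, a homeobox gene that sustains myeloid leukaemia, went from 1880 ± 72.3 to 1250 ± 34.2 (n = 3 each) and Hoxa3 from 193 ± 14.9 to 104 ± 14.5. Of 12 PRC2 subunit genes 7 fell and 2 rose (7 and 2 adjusted over the list alone), with Rbbp4 at 0.774 and Suz12 at 0.815 times DMSO. Of 19 neutrophil and granule genes 12 rose and 6 fell (12 and 6 adjusted over the list alone). The collagenase Mmp8 rose 4.01-fold and the calprotectin genes S100a8 and S100a9 rose 6.48-fold and 27.9-fold. S100a9 was at 14.7 in DMSO and 410 with UNC1999, so its fold rests on a low control level. These 3 lists passed camera (adjusted p = 0.0106, 0.0238 and 0.0238), but not with an estimated correlation (adjusted p = 0.063, 0.11 and 0.077 with an estimated correlation). Of 8 genes for CDK inhibitors and the RB family 2 rose and 3 fell, and the list did not pass (camera adjusted p = 0.763), although Cdkn2a, the locus of p16INK4a and p19ARF, rose 2.99-fold, from 100 ± 12.2 to 299 ± 29.6. In total limma called 5118 of 10694 genes, 2552 higher and 2566 lower (2272 and 2956 with quantile normalisation, 2717 and 2605 with no filter), of which 266 and 27 differed at least 2-fold in normalised counts, and 8 of 16 lists tested did not pass (camera adjusted p from 0.051 to 0.884).

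JQEZ5 gave a smaller response led by many of the same names. Gpnmb rose 6.22-fold, to 32500 ± 427 (n = 3), Spp1 3.38-fold, Irg1 3.35-fold, Lrp12 3.86-fold, and the immunoglobulin-like receptor genes Lilr4b and Lilrb4a 3.76-fold and 2.93-fold. The last 2 are close paralogs, so the split of reads between them is uncertain. Cxcr2 fell to 228 ± 19 against 797 ± 28.9 in DMSO, and Rn7sk, Itgb3, Mir6236, the B cell receptor component Cd79b and Xirp1 fell to 0.495, 0.487, 0.607, 0.357 and 0.38 times DMSO (limma adjusted p for these 12 genes from 5.54e-19 to 4.15e-05). Of 30 monocyte and macrophage genes 20 rose and 4 fell (21 and 4 adjusted over the list alone), with Cd68 up 2.28-fold and lysozyme Lyz2 up 1.87-fold.

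Of the G2 and M phase genes 20 of 30 fell (25 adjusted over the list alone), with Top2a at 0.814 and Mki67 at 0.818 times DMSO after JQEZ5. Of the S phase genes 14 of 30 fell (16 adjusted over the list alone), with Cdc6 at 0.765. Of 25 integrated stress and unfolded protein response genes 9 rose and 2 fell (11 and 5 adjusted over the list alone), with the cystine transporter Slc7a11 up 3.48-fold and the transcription factors Atf5 and Atf4 up 2.2-fold and 1.26-fold. Of the HOX genes 5 of 10 fell (6 adjusted over the list alone), with Hoxa9 at 0.746 times DMSO, and of 19 neutrophil and granule genes 9 rose and 4 fell (9 and 4 adjusted over the list alone), with Olfm4 up 2.31-fold. Cd74 and H2-Oa, 2 of the 3 tested genes of MHC class II presentation, fell to 0.573 and 0.62 times DMSO, again 2 adjusted over the list alone. These lists and the monocyte list passed camera, with adjusted p from 4.21e-14 to 0.00937, and adjusted p from 0.018 to 0.043 with an estimated correlation.

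Of the MYC and ribosome biogenesis genes 9 of 30 rose with JQEZ5 and none fell (9 adjusted over the list alone), with the translation factor Eif4a1 up 1.18-fold and the chaperone gene Hspe1 up 1.16-fold (camera adjusted p = 0.0403; adjusted p = 0.077 with an estimated correlation). That list missed the threshold without DMSO replicate 1, JQEZ5 replicate 1 or JQEZ5 replicate 3 (camera adjusted p = 0.0605, 0.0544 and 0.0534). Of 12 PRC2 subunit genes 3 fell (3 adjusted over the list alone), with Rbbp4 at 0.911 and Rbbp7 at 0.901 times DMSO. Of 17 interferon-stimulated genes 4 fell and 2 rose (7 and 2 adjusted over the list alone), with Stat2 at 0.82. Both lists had a camera adjusted p of 0.0472, with adjusted p = 0.15 and 0.099 with an estimated correlation. Without DMSO replicate 1 these were 0.101 and 0.0931; leaving out any JQEZ5 library also ended the call of the PRC2 list (0.0544 to 0.0644), and leaving out DMSO replicate 2 or JQEZ5 replicate 1 or 3 that of the interferon list (0.0545 to 0.0733), as did median centring (0.0589). In total limma called 2529 of 10694 genes, 1403 higher and 1126 lower (1198 and 1337 with median centring, 1190 and 1315 with quantile normalisation), of which 95 and 21 differed at least 2-fold, and 6 of 16 lists did not pass (camera adjusted p from 0.143 to 0.897).

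**Figure D2:**
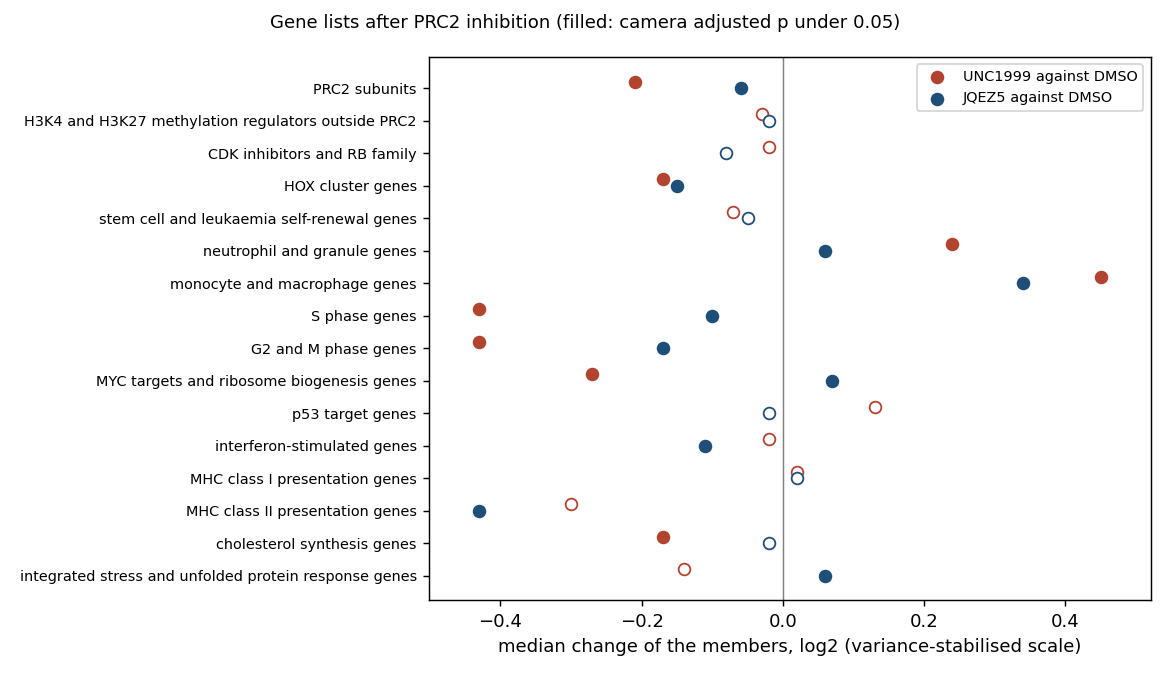
Median log2 change of the members of each tested gene list (horizontal axis, variance-stabilised scale) after UNC1999 and after JQEZ5, each against DMSO (3 libraries per group). Filled points passed camera at an adjusted p under 0.05 with a preset correlation. The MYC and ribosome biogenesis list lies at -0.27 with UNC1999 and at 0.07 with JQEZ5.

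The inhibitors, given at the same dose for the same time, were also tested against each other. Fibronectin (Fn1) was 4.39-fold higher with UNC1999 than with JQEZ5 (3620 ± 164 against 826 ± 19.6, n = 3 each), Arg1 3.57-fold, the acute-phase gene Saa3 2.61-fold and the collagenase Mmp13 3.86-fold. The granulocyte progenitor genes Ms4a3 and Mpo were at 0.549 and 0.649 times the JQEZ5 level, and Bcat1 and the serine synthesis gene Psat1 at 0.567 and 0.648 (limma adjusted p for these 8 from 8.26e-14 to 3.22e-08). Monocyte and macrophage genes were higher with UNC1999 in 25 of 30 cases and lower in none, S phase genes lower in 29 of 30, G2 and M phase genes lower in 29 of 30 and MYC and ribosome biogenesis genes lower in 28 of 30, in each list the same count adjusted over the list alone. Ncl, the gene of nucleolin, was at 0.726 times the JQEZ5 level. These lists had camera adjusted p from 4.7e-18 to 3.75e-16 (adjusted p from 0.00097 to 0.0035 with an estimated correlation).

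Stress response genes were lower with UNC1999 than with JQEZ5 in 13 of 25 and higher in 4 (13 and 5 adjusted over the list alone), led by Phgdh, Shmt2 and Psat1, enzymes of serine and glycine synthesis, and Asns, asparagine synthetase. Cholesterol synthesis genes were lower in 10 of 22 (10 adjusted over the list alone). Both had a camera adjusted p of 0.000137 (adjusted p = 0.011 with an estimated correlation). Of 20 p53 target genes 10 were higher and 2 lower (12 and 2 adjusted over the list alone), with Plk2 1.69-fold higher (camera adjusted p = 0.00929; adjusted p = 0.046 with an estimated correlation). Of 17 interferon-stimulated genes 6 were higher (6 adjusted over the list alone), and of 12 PRC2 subunit genes 6 were lower and 1 higher (6 and 2 adjusted over the list alone). Those lists had camera adjusted p of 0.0138 and 0.0462, and adjusted p = 0.054 and 0.15 with an estimated correlation; the PRC2 list missed the threshold without JQEZ5 replicate 1 or 3 or UNC1999 replicate 1 or 3 (0.0504 to 0.0784).

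Some responses did not pass a test between the compounds, which does not show that they were equal. The HOX list missed camera between them (adjusted p = 0.423) but passed fry (adjusted p = 0.0033). Of its 10 genes 1 was higher and 2 lower with UNC1999 (0 and 2 adjusted over the list alone). Hoxa9 was lower with UNC1999 by a log2 difference of -0.15 (95% interval -0.22 to -0.07, limma adjusted p = 0.00419). For Hoxa3 the interval of the difference was -0.20 to 0.09, for Itgb3 -0.18 to 0.12, for Xirp1 -0.23 to 0.01 and for Cd79b -0.02 to 0.26, none past the test (limma adjusted p from 0.156 to 0.81). Limma called 3892 of 10694 genes between the inhibitors, 2003 higher and 1889 lower with UNC1999 (1801 and 1999 with quantile normalisation), with 59 and 7 at least 2-fold apart. Against DMSO the inhibitors shared 1161 genes called higher and 781 called lower, where independent lists would share 335 and 270, and 83 genes were called in opposite directions, against 605 for independent lists. Across genes, which are not independent replicates, the changes correlated at r = 0.78, against 0.50 for simulated unchanged groups that share the same controls, and their covariance was 0.0328 against a simulated 0.00158. The 3 DMSO libraries could not be split into groups of at least 2, so part of the excess may come from the shared controls. Among the shared calls 79% were larger with UNC1999, and the median JQEZ5 change was 0.68 of the UNC1999 change.

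The knockdown asked what Kdm5b loss does to NUP98-NSD1 cells. The shKdm5b libraries were set against an empty vector only. Kdm5b loss therefore cannot be told apart from other effects of the shRNA or from the origin of the shKdm5b cells. Mcpt8, a basophil protease, rose 36.7-fold, from 72 ± 8.99 with shEV to 2640 ± 175 with shKdm5b (n = 3 each). Igll1, a surrogate light chain of early B cells, was at 630 ± 85.4 against 11.8 ± 1.4, the chemokine receptor Ccr2 rose 6.64-fold, the mucin Muc13 3.76-fold, haem oxygenase Hmox1 3.71-fold and P2rx3 4.73-fold. Cyfip2, Fcrls, Aif1, the phagosomal metal transporter Slc11a1, Wbp5 and the mitochondrial cyclophilin Ppif fell to 0.273, 0.243, 0.221, 0.348, 0.27 and 0.367 times shEV. Over these 12 genes the limma adjusted p ran from 1.04e-08 to 0.000133. Ezh2 had a log2 difference of -0.03 ± 0.04 (limma adjusted p = 0.607).

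Of 30 MYC target and ribosome biogenesis genes 22 fell with shKdm5b and none rose (24 and 2 adjusted over the list alone), with the pyrimidine synthesis gene Cad at 0.602 and the RNA polymerase I subunit Polr1a at 0.709 times shEV. Of 30 G2 and M phase genes 13 rose (14 adjusted over the list alone), Nusap1 by 1.49-fold and Ccnb2 by 1.3-fold. Of 14 neutrophil and granule genes 8 rose and 2 fell (9 and 3 adjusted over the list alone), with neutrophil elastase Elane up 1.93-fold and Mmp8 2.24-fold, and of 8 CDK inhibitor and RB family genes Cdkn2c, Cdkn1a and Rb1 rose (4 higher and 1 lower adjusted over the list alone). These lists had camera adjusted p of 3.13e-07, 0.000108, 0.00129 and 0.048. None passed with an estimated correlation (camera adjusted p = 0.2, 0.24, 0.2 and 0.24 with an estimated correlation). Each passed with fry (fry adjusted p = 0.00084, 0.0037, 0.00089 and 0.0031). The CDK inhibitor list missed the threshold without shEV replicate 3 (camera adjusted p = 0.0835) or shKdm5b replicate 3 (0.0518) and with no filter on low values (0.119). Monocyte and macrophage genes split, 9 higher and 12 lower of 28 (12 and 12 adjusted over the list alone), with a median of -0.09 and a mean of 0.10 (camera adjusted p = 0.965). Ly6c2 and Ly6c1, near-identical genes whose reads could be exchanged, were 2.48-fold and 2.46-fold higher.

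In total limma called 3509 of 10810 genes after the knockdown, 1624 higher and 1885 lower (1746 and 1705 with quantile normalisation), with 103 and 80 at least 2-fold apart. The count depended on single libraries. It was 1907, 2006 and 2017 without shEV replicate 1, 2 and 3, and 5556 without shKdm5b replicate 1, a library that differed from shKdm5b replicates 2 and 3 with a chi-square per degree of freedom of 18.3 and 17.0, against 2.19 to 2.74 between shEV libraries.

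Kdm5b was overexpressed in MLL-AF9 cells, as wild type or as H499A, to ask what the protein does and what depends on its demethylase activity. Lysozyme Lyz2 rose 4.22-fold with WT, from 5130 ± 281 to 21700 ± 835 (n = 2 each), the macrophage colony-stimulating factor receptor Csf1r 4.3-fold, the NADPH oxidase subunit Cybb 3.25-fold, the lipid droplet protein Plin2 3.65-fold and Dmrta2 4.69-fold. Gem, the desaturase Scd2, Spns2, Cnn3 and the integrin Itga4 fell to 0.101, 0.277, 0.202, 0.259 and 0.365 times EV (limma adjusted p for these 10 from 1.42e-26 to 2.79e-22). Of 21 monocyte and macrophage genes 19 rose and 2 fell, of 23 cholesterol synthesis genes 20 fell, with Cyp51 at 0.469, and of 30 MYC and ribosome biogenesis genes 27 fell, with Ldha at 0.562 and Npm1 at 0.7. Of 30 S phase genes 25 fell and 1 rose (25 and 2 adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at 0.653. The counts of the first 3 lists were the same adjusted over the list alone.

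Of 24 stem cell and leukaemia self-renewal genes 17 fell with WT and 5 rose, among them the receptor gene Flt3 at 0.344, Angpt1 at 0.32 and Sox4 at 0.529 times EV. Of 17 p53 target genes 14 rose and 2 fell, with Ccng1 up 1.97-fold, and of 8 CDK inhibitor and RB family genes 6 rose and 1 fell, with Cdkn2a up 5.17-fold, from 61.3 ± 0.246 to 317 ± 2.01. Of 15 neutrophil and granule genes 10 rose and 5 fell, with the integrin Itgam up 2.04-fold. The counts in these 4 lists were the same adjusted over the list alone. The 8 lists named for WT passed camera, with adjusted p from 1.47e-15 to 0.0066, but none with an estimated correlation (adjusted p from 0.10 to 0.38 with an estimated correlation), and the neutrophil list also missed it with no filter on low values (camera adjusted p = 0.46). Ezh2 fell by 13.9% with WT (limma adjusted p = 5.78e-07). The 9 other lists did not pass with WT (camera adjusted p from 0.0534 to 0.966), nor did 9 with H499A (0.192 to 0.996). In total limma called 5881 of 9458 genes, 2817 higher and 3064 lower (2322 and 3669 with median centring, 3386 and 3326 with no filter), with 267 and 114 at least 2-fold apart. The 2 WT libraries differed with a chi-square per degree of freedom of 9.98, against 1.77 for EV and 1.5 for H499A.

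Many myeloid genes were also higher with the mutant. Ly6c2 rose 5.63-fold with H499A, from 790 ± 19.1 to 4450 ± 57.4 (n = 2 each), Ly6c1 6.32-fold, the transcription factor gene Sp9 20.6-fold, the protease inhibitor Slpi 3.86-fold, coagulation factor F10 4.75-fold and Colec12 4.83-fold. Bhlhb9 was at 2.86 ± 1.42 against 640 ± 20.2 in EV, and Muc13, the desaturase Fads2, Decr1, Cd48 and Elane fell to 0.241, 0.172, 0.0481, 0.22 and 0.327 times EV (limma adjusted p for these 12 from 1.09e-25 to 1.06e-17). Of 21 monocyte and macrophage genes 20 rose (21 adjusted over the list alone), of 19 interferon-stimulated genes 18 rose, with Oas1a up 3.61-fold and Oas2 6.14-fold, and all 6 HOX genes tested rose, with Hoxa11 up 2.67-fold and Hoxa9 1.26-fold. Of 23 cholesterol synthesis genes 21 fell, with Insig1 at 0.352, and of 30 S phase genes 17 fell and 1 rose. Of 24 stem cell genes 15 fell and 4 rose, with Cd34 at 0.642 and Pbx3 up 6.33-fold. Of 15 neutrophil and granule genes 11 rose and 2 fell, and of 17 p53 target genes 12 rose and 2 fell (13 and 2 adjusted over the list alone). Other counts here were the same adjusted over the list alone. These 8 lists passed camera (adjusted p from 2.26e-22 to 0.00367), and none did with an estimated correlation (adjusted p from 0.057 to 0.36 with an estimated correlation). Ezh2 fell by 10.8% with H499A (limma adjusted p = 4.42e-05), and limma called 4689 of 9458 genes, 2148 higher and 2541 lower (1939 and 2806 with median centring, 2737 and 2671 with no filter), with 211 and 72 at least 2-fold apart.

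**Figure D3:**
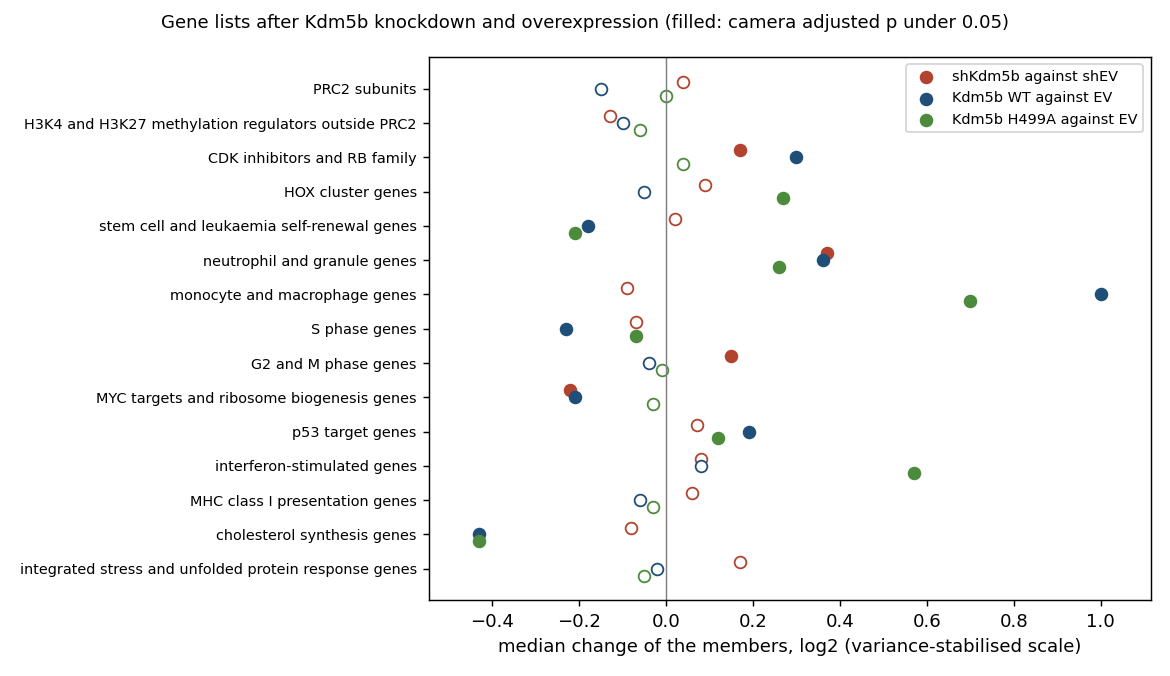
Median log2 change of the members of each gene list tested in all 3 comparisons (horizontal axis, variance-stabilised scale) after Kdm5b knockdown (3 libraries per group) and after WT or H499A overexpression (2 libraries per group), each against its own vector control. Filled points passed camera at an adjusted p under 0.05 with a preset correlation; none did with an estimated correlation. Interferon-stimulated genes lie at 0.08 with WT and 0.57 with H499A.

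The direct test between WT and H499A separated these groups at the same vector and cell line but not at the same Kdm5b level. The lectin Lgals3 was at 22.7 ± 5.39 with WT and 1470 ± 20 with H499A (n = 2 each), Sp9 at 8.69 ± 2.56 and 925 ± 66.6, the sialic acid receptor Cd33 at 405 ± 1.87 and 2560 ± 10.2, and Ly6c2 at 975 ± 35.2 and 4450 ± 57.4. Adrbk2, Bhlhb9 and Ppic were at 707 ± 3.9, 584 ± 9.56 and 543 ± 18.9 with WT and at 7.11 ± 0.862, 2.86 ± 1.42 and 1.88 ± 1.29 with H499A (limma adjusted p for these 7 genes from 7.85e-25 to 1.04e-21). Interferon-stimulated genes were lower with WT in 16 of 19 and higher in 1 (17 and 1 adjusted over the list alone), with Oas2 at 0.0842 and Ddx58 at 0.265 times H499A, and HOX genes were lower in 6 of 6 (6 adjusted over the list alone), with Hoxa9 at 0.625. MYC and ribosome biogenesis genes were lower with WT in 28 of 30 (29 adjusted over the list alone) and S phase genes in 20 of 30, with 1 higher (20 and 2 adjusted over the list alone). Monocyte and macrophage genes were higher with WT in 17 of 21 and lower in 4 (17 and 4 adjusted over the list alone): Lyz2 was 2.26-fold higher, while F13a1, Ly6c1 and Ly6c2 were at 0.525, 0.201 and 0.219 times H499A. These 5 lists had camera adjusted p from 5.41e-10 to 3.23e-05, and adjusted p from 0.097 to 0.30 with an estimated correlation. Limma called 5146 of 9458 genes, 2663 higher and 2483 lower with WT (2241 and 2841 with median centring, 2479 and 2488 with quantile normalisation, 2892 and 2914 with no filter, 1736 and 1924 with the stricter filter), with 107 and 141 at least 2-fold apart; for Ezh2 the log2 difference was -0.05 ± 0.03 (limma adjusted p = 0.146), which passed with median centring (0.0466) or without WT replicate 1 (0.0344). The 12 other lists tested did not pass (camera adjusted p from 0.059 to 0.802).

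WT and H499A shared 1440 genes called higher and 1642 called lower against EV, where independent lists would share 640 and 823, and 433 genes were called in opposite directions, against 1453. Across genes the changes correlated at r = 0.60, against a simulated 0.50 for unchanged groups sharing the EV libraries, with a covariance of 0.0296 against 0.000652. The 2 EV libraries could not be split, so part of the excess may come from the shared controls.

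To link the experiments, genes called the same way by both inhibitors were tested as sets after knockdown and overexpression. Genes called after knockdown were tested as sets in the other comparisons (16 camera tests in all). Counts for independent lists take every gene as equally likely to be called, so an excess above them need not mark a link. Of 926 genes raised by both inhibitors and tested in MLL-AF9 cells, 489 were higher with WT, against 278 for independent lists, and 400 with H499A, against 208. Lower were 210 with WT, against 294, and 201 with H499A, against 245. As a set they were higher in both (camera adjusted p = 4.06e-06 and 9.28e-05; adjusted p = 0.0563 for each with an estimated correlation). After the knockdown 249 genes of this set were higher, against 159 for independent lists, and 216 lower, against 185 (camera adjusted p = 0.501). Limited to genes that changed by at least 1 log2 unit with both inhibitors, at most 23, the set was higher (camera adjusted p = 0.00122). Genes lowered by both inhibitors did not fall as a set. Of 723 tested in MLL-AF9 cells, 264 were higher and 249 lower with WT, against 217 and 230 for independent lists, and 232 higher and 204 lower with H499A, against 162 and 191 (camera adjusted p = 0.609 and 0.501, and 0.336 after the knockdown). After the knockdown 186 of the genes lowered by both inhibitors were higher, against 112, and 142 lower, against 131. Genes called after the knockdown did not pass as a set in the WT or H499A comparisons (camera adjusted p from 0.451 to 0.834). With a fold minimum of 1 log2 unit those raised by it were higher with H499A (0.00608) and, turned in direction, lower with WT than with H499A (0.0101). With UNC1999 515 of the raised genes were higher, against 350 for independent lists, and 595 of the lowered ones lower, against 442, but neither set passed (camera adjusted p = 0.215 and 0.548), nor did they with JQEZ5 (0.849 and 0.834). There the raised genes were in excess both ways, 280 higher against 195 and 257 lower against 160, and of the lowered ones 275 were higher against 227 and 205 lower against 187. Across 9108 genes the knockdown and WT changes correlated at r = -0.04 (Spearman's rho 0.01), and of 2011 genes called in both, 1047 went the same way and 964 the opposite way. The UNC1999 and knockdown changes correlated at r = 0.05, with 1110 genes the same way and 785 the opposite way, and the UNC1999 and WT changes at r = 0.29, with 2198 and 918. For JQEZ5 r was 0.01 with the knockdown (485 the same way and 532 the opposite way) and 0.05 with WT (817 and 788). The H499A changes correlated with those of UNC1999 at r = 0.24 (1561 the same way and 931 the opposite way). With JQEZ5 their r was 0.08 (701 and 639), and with the knockdown -0.01 (783 and 856). Genes are not independent replicates.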

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

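The voom fit was chosen after the data were seen, and all other alternatives here were set beforehand. Calls in the 7 comparisons, in the order UNC1999, JQEZ5, UNC1999 against JQEZ5, shKdm5b, WT, H499A and WT against H499A, stayed within 1.5 times their count in every alternative except a fold minimum and the knockdown's leave-one-out fits. A fold minimum of 1 log2 unit left 97, 25, 11, 46, 70, 51 and 37 genes, since it admits fewer, and overlaps of 24 for the inhibitors and 14 for WT and H499A. Leave-one-out counts ran from 4362 to 5082, 1830 to 2184, 3130 to 3827, 1907 to 5556, 4968 to 5478, 3720 to 3841 and 4153 to 4746. For the knockdown they were 1907, 2006 and 2017 without shEV replicates 1, 2 and 3 and 5556 without shKdm5b replicate 1; the cause was not tested. Where 1 library was left in a group, its spread was taken from the others. The replicate block gave 5028, 2382, 3775, 3491, 5955, 4769 and 5238 calls. Deviations from group means correlated at r from -0.15 to 0.22 between libraries of 1 number and from -0.19 to 0.26 between those of different numbers. No pairing by number was seen, but with 2 or 3 libraries per group a pairing is not excluded. With the block the PRC2 and interferon lists with JQEZ5 (camera adjusted p = 0.0548 each) and Cd74 between the inhibitors (limma adjusted p = 0.0527) missed the threshold. Voom gave 5044, 2591, 3924, 3538, 5824, 4682 and 5152.

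Of 530 comparisons for 52 called lists, 475 kept direction and side of the threshold and 55 lost the call. With an estimated correlation 5 lists passed for UNC1999 and 0 for shKdm5b, WT, H499A and WT against H499A, where camera with the preset correlation passed 8, 4, 8, 8 and 5. With fry 15 passed between the inhibitors, 8 for shKdm5b, 15 for WT, 14 for H499A and 12 between WT and H499A. All 52 called lists kept their call with fry. Leave-one-out fits of shKdm5b passed 3 (without shEV replicate 3) to 7 (without shKdm5b replicate 2). The genes raised by both inhibitors had, as a set, a camera adjusted p of 0.00122 after the knockdown with a fold minimum, and of 0.0563 with WT and with H499A with an estimated correlation. With a fold minimum the genes raised by the knockdown had 0.00608 with H499A and, turned to lower, 0.0101 between WT and H499A. The cause was not tested. Of 7342 comparisons for named genes 7255 were the same, 82 lost and 2 gained the call, and 3 turned direction, all for Ezh2 with JQEZ5, at log2 values of 0.0248, 0.0142 and 0.0076 without DMSO replicate 3, JQEZ5 replicate 1 and JQEZ5 replicate 3 (leave-one-out range -0.024 to 0.0248), none of them called. Pseudocount and DESeq2 alternatives, set for a knockdown table of linear values or counts, were not run; the recovered counts were fitted with voom. Depth limits Kdm5b itself in the knockdown, at 17 to 34 reads per shKdm5b library.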

Other observations

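Most lists of markers of other lineages had fewer than 3 tested members and no set test. Mcpt8, the 1 tested marker of mast cells, basophils and eosinophils in the knockdown, had the largest log2 rise of the genes named there, yet it fell to 0.178 times EV with WT and 0.318 times with H499A (n = 2 each; limma adjusted p = 1.36e-13 and 8.66e-11). Of 3 B cell markers Igll1 rose and Cd79b fell to 0.21 times shEV (camera adjusted p for the list 0.822), and Cd79b was at 0.718 times EV with WT and 2.08 times with H499A. Of the megakaryocyte markers Vwf rose 7.44-fold with UNC1999 and 3.68-fold with JQEZ5, while Itgb3 fell with both. The erythroid marker Tfrc, the transferrin receptor, fell to 0.897 times DMSO with UNC1999, 0.599 times EV with WT and 0.719 times with H499A. Of T and NK cell markers none was tested with the inhibitors, and Gata3 fell to 0.588 times shEV in the knockdown. Of dendritic cell markers Tcf4 fell and Bst2 rose with both inhibitors, and the list did not pass in MLL-AF9 cells (camera adjusted p from 0.336 to 0.694). Of stromal and endothelial markers Pecam1 and Acta2 fell to 0.659 and 0.823 times DMSO with UNC1999 and to 0.772 and 0.82 times with JQEZ5, and Pecam1 rose 1.48-fold with WT. Of 55 developmental transcription factors, 5 were in the inhibitor table and 1 was tested, Pax8, which fell to 0.807 times DMSO with UNC1999 (limma adjusted p = 0.0175), a call lost without DMSO replicate 1 (0.063) or UNC1999 replicate 2 (0.0851). Six4 rose 2.6-fold with WT (limma adjusted p = 1.37e-10).

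Some chromatin and stem cell genes moved in lists that did not pass. Bmi1, a subunit of the Polycomb complex PRC1, rose 1.79-fold with UNC1999 and 1.7-fold with JQEZ5 (n = 3 each; limma adjusted p = 1.34e-08 and 1.61e-07), while stem cell genes did not pass as a list (camera adjusted p = 0.299 and 0.604). Regulators of H3K4 and H3K27 methylation outside PRC2 were 5 higher and 6 lower of 18 with UNC1999 (camera adjusted p = 0.884), with the methyltransferase genes Kmt2c and Kmt2d up by 0.41 ± 0.04 and 0.37 ± 0.05 log2 units, and Kmt2d was at 0.719 times shEV in the knockdown. MHC class I genes passed in no comparison, with 6 higher and 4 lower of 20 with UNC1999 (camera adjusted p = 0.763). In MLL-AF9 cells Cd74, the class II invariant chain, rose 2.52-fold with WT and 5.19-fold with H499A. Integrated stress genes after the knockdown were 12 higher and 6 lower of 27 (camera adjusted p = 0.0946).

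In the tests below, all but that of a graded response to Kdm5b mRNA were chosen after the result was seen. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 5118 genes for UNC1999, 2529 for JQEZ5, 3892 between the inhibitors and 3509 for shKdm5b, and the highest other split 0, 0, 1 and 0, so 1 split of 10 reached the real count in each. The other splits mix libraries of the 2 groups, so differences between the groups widen their spread and their low counts decide nothing.

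H499A differed from WT at 5146 genes, about as many as either differed from EV. A graded response to Kdm5b mRNA, from EV over H499A to WT, would put H499A in the middle, and it was there in 46.9% of 7077 differing genes, with EV in the middle in 28.0% and WT in 25.2%. Each transduced population may also have grown from few cells that carried genes switched on or off: of 23 genes at least 10-fold apart from EV in either population, with a mean of at least 200 normalised counts in the higher group and Kdm5b left out, 2 switched the same way in both. Dose, lost demethylase activity and the origin of the cells cannot be told apart. Kdm5b mRNA was unequal between the constructs, and the labels do not say whether the libraries of a construct came from 1 population or more.

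JQEZ5 changes ran with those of UNC1999 and were smaller. Random spread of the shared DMSO libraries alone is argued against by the covariance of 0.0328 across genes, against 0.00158 in simulated unchanged groups. Those simulated groups carried only the spread between libraries of a group. A shift common to all DMSO libraries was not simulated, so it stays open as a source of part of the shared changes. A lower effective dose with 1 scale factor of 0.68 for all genes is argued against by 28 of 30 MYC and ribosome biogenesis genes whose interval with JQEZ5 lay above the scaled value. That factor comes from genes called with both compounds and may be too high for others, but 7 of the 30 fell with UNC1999 and rose with JQEZ5, also with median centring or quantile normalisation, which no positive factor gives. A dose response that differs between groups of genes, and a different action of each compound, stay open, since 1 dose and 1 time were sampled.

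Lars2 and Mir6236 were among the lowest genes after both inhibitors, Lars2 at 34800 in DMSO, 22000 with JQEZ5 and 17500 with UNC1999. Carry-over of rRNA-like and other RNA without a poly(A) tail may explain this. Lars2 is annotated as protein-coding, and whether its reads come from such RNA was not tested. The deviations of 5 genes (Lars2, Mir6236, Rn7sk, Gm26917 and Gm42418) from their group means correlated at a median r of 0.8 over 21 libraries. This r was 0.61 without the 2 WT libraries and 0.7 in the 9 inhibitor libraries alone. The 95th percentile of 10000 random gene sets was 0.39, 0.39 and 0.37. AY036118, set beside them, was not tested in every experiment and is left out. Reads shared between the annotated transcripts of Lars2 and Mir6236 are argued against by 0 shared 31-base words. In the knockdown the 5 did not all move together: Lars2 was at 9220 with shEV and 26600 with shKdm5b and Mir6236 at 1320 and 3400, but Rn7sk at 1320 and 1400, Gm26917 at 48100 and 39800 and Gm42418 at 15100 and 18400, which carry-over common to all of them does not account for. With both inhibitors the 5 lay below DMSO, but Rn7sk was lower with JQEZ5 (546) than with UNC1999 (804), the reverse of Lars2. The log2 difference of UNC1999 from JQEZ5 was 0.42 for Rn7sk (limma adjusted p = 0.000165) and -0.34 for Lars2 (limma adjusted p = 0.014). Common carry-over does not account for that order either. An effect of the treatments on these transcripts themselves stays open.

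Kdm5b was at 40.1 ± 1.05 CPM (counts per M counts) in DMSO and 2.52 ± 0.607 in shEV, both labelled NUP98-NSD1 cells, and at 6.49 ± 0.52 in MLL-AF9 cells with EV, an untested difference between separately normalised tables. The labels do not say whether the DMSO and shEV libraries came from the same NUP98-NSD1 line or batch of cells, so comparisons between the inhibitor and knockdown experiments cross this difference. Other genes chosen after their values were seen were Fn1, at 49.9, 0.282 and 2.4, Ccr1, at 119, 0.452 and 18.2, and Hoxa9, at 124, 207 and 202 CPM in DMSO, shEV and EV. AY036118 and Lars2, chosen after their values were seen, were at 30800 and 21300 in WT replicate 1 and at 7350 and 7190 in WT replicate 2.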
